A study of Mus musculus with 6 samples.

How the data were processed

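Mesenchymal stromal cells from mouse bone marrow were profiled by RNA sequencing in 6 libraries, 3 from control cultures and 3 from cultures fed apoptotic thymocytes. Per the labels' protocols, marrow cells lacking haematopoietic lineage markers, CD45 and CD31 and carrying CD51 were sorted, expanded at 2% oxygen and used at passage 2 or 3. Wells of the fed group received 5000000 dye-labelled apoptotic thymocytes each in medium and were kept for 24 h at 5% oxygen. Control wells received no thymocytes, and the labels do not say whether they received new medium or were moved to 5% oxygen at the same time. After washing, both groups were sorted by flow cytometry, and label-positive cells were collected from the fed cultures. Per the labels, 200 ng of total RNA entered a stranded library preparation that selects polyadenylated RNA.

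The deposited values are raw counts per gene symbol, whole numbers whose totals differ between libraries. Per the submitters' processing notes, the authors used MultiQC 1.5, Trimmomatic 0.36, STAR 2.6.0c and featureCounts of Subread 1.6.1 with the mouse build GRCm38. The annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here. Genes with near-identical copies, such as Serpina3n, Lyz2 and the H2 genes, and genes that overlap another gene are therefore less certain than the rest. The table held 53735 features. Names that read as dates, as left by spreadsheet software, made up 27 of them and held 0.227% of the counts. They stayed in the library totals and the fit but are not named. Symbols were matched to GENCODE release M21 on GRCm38 for coordinates. Of the names, 28509 matched a symbol, 259 matched through a single synonym and 24967 did not match, and the matched names held 98.3% of the counts.

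Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with default settings, libraries were scaled by TMM, and fed was compared with control by the quasi-likelihood F-test with robust estimation and no replicate block. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and 13092 genes were tested. CPM are counts relative to the TMM-scaled library total, times 1e6. Errors beside CPM are SDs over libraries, and errors beside log2 fold changes are standard errors derived from the F statistic. The labels do not say whether libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries of a group differed from each other by more than sampling noise, so each was kept as its own library. Such a difference cannot show that they came from separate cultures or animals. The common coefficient of variation estimated by edgeR was low, at 3.94%.

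Before the data were examined, 40 gene lists were fixed, 32 of functions and 8 of cell types the cultures or the sort could hold. Lists with at least 3 tested members, 38 in all, were tested by camera in limma 3.58.1 with the preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stood camera with a correlation estimated for each list, and fry. Camera compares a list with the other genes. The fry test asks whether the members move, on balance, in a single direction and does not compare the list with other genes. For each list the members passing over all genes tested and those passing when adjusted over the list alone were counted.

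The rule for named genes was also fixed then. It takes the 12 genes with the largest and the 12 with the most negative log2 fold change among called genes with a mean of at least 2 CPM and no overlap between the groups, leaving out predicted genes, clones, pseudogenes and receptor segments. It adds up to 4 called members of each list with the smallest adjusted p, and a panel of Mertk, Axl, Abca1, Cdkn1a, Cdkn2a, Dnm1l, Mfn2, Opa1, Runx2, Alpl, Cxcl12, Kitl and Il6. Genes named outside this rule were chosen after their values were seen, and some genes the rule takes are not reported here.

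On simulated counts with the means and library sizes of these samples (13005 genes, 50 changed genes per size), the test recovered 44.0% of genes changed by 0.25 on the log2 scale, 78.0% at 0.5, 92.0% at 1 and 98.0% at 2. Of 170 genes called there, 14 were unchanged. Only 200 genes were changed there, against 5175 called in these data. The adjustment was therefore stricter, and the recovered shares may be too low for these data. Alternatives were other normalizations (RLE, upper quartile, library totals only), other filters, DESeq2 1.42.0, limma-voom, a fit without robust estimation, the replicate number as a block, an adjusted p under 0.01, a test against a 1.5-fold change, the thymocyte markers left out, and each library left out in turn. Lists chosen after the data were seen were tested in the same way, adjusted over these 9 lists alone. They were also set against 10000 random lists matched on mean expression in 20 bins. Figures were drawn with matplotlib 3.10.9.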

Results

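The series asks how phagocytosis affects cells of the mesenchymal and osteoblast lineage. Stromal cells grown from mouse bone marrow were fed apoptotic thymocytes, and cells that had taken up the label were compared by RNA sequencing with cells of unfed cultures. There were 3 control and 3 fed libraries. Their totals were 21949519, 21466553 and 19069074 counts in the control group and 20034583, 21520141 and 22410047 in the fed group, so depth was similar in both. The first principal component held 56.3% of the variance and separated the groups. The second held 14.3% and set control replicate 3 apart from the other control libraries.

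In fed cells, genes of DNA replication and mitosis rose, and the list of contractile and TGF-beta targets was called higher. Genes of the hypoxia response, glycolysis, the lysosome, the integrated stress response, the fibrillar matrix and NF-kB feedback fell. These are calls of camera with its preset correlation, and the smallest was adjusted p = 0.265 with an estimated correlation. The changes were many and mostly small. Of 13092 genes tested with edgeR's quasi-likelihood test, 5175 (39.5%) changed at an adjusted p under 0.05, 2682 higher and 2493 lower in fed cells. The median log2 fold change was 0.29 among the genes called higher and -0.27 among those called lower. A change of at least 1.5-fold was seen in 694 called genes (362 higher, 332 lower) and of at least 2-fold in 148 (61 higher, 87 lower). The groups did not overlap for 6430 genes, 49.1% of those tested, where chance gives 10%. Tested against a 1.5-fold change in place of no change, 88 genes passed.

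Among the 12 genes with the largest increase were Serpina3n, a serine protease inhibitor, the ETS transcription factor Etv4, Id1, an inhibitor of basic helix-loop-helix factors, and Car8. Serpina3n (chromosome 12, 104406729 to 104414329) rose from 31.8 ± 3.89 to 86.6 ± 8.26 CPM (SD, n = 3), a log2 fold change of 1.44 ± 0.10 (SE, adjusted p = 4.22e-05). Etv4 rose from 4.16 ± 0.940 to 10.3 ± 0.628 CPM. Id1 (chromosome 2, 152736251 to 152737410) rose from 18.2 ± 1.39 to 41.6 ± 1.79 CPM. Lyz2, the lysozyme of macrophages and granulocytes, was also in this group, at 7.47 ± 0.866 CPM in fed cells. Other members were Tmem200a, Aunip, Olfm2 and Ubash3b, with log2 fold changes between 1.11 and 1.28. The highest fold belonged to Arc, an immediate-early gene, with a log2 fold change of 1.90 ± 0.54 and an adjusted p of 0.0455. Its call was lost without control replicate 2 (adjusted p = 0.140), control replicate 3 (0.137) or fed replicate 2 (0.0534).

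The 12 genes with the largest decrease were led by Arntl and Npas2, transcription factors of the circadian clock. Arntl (chromosome 7, 113207465 to 113314126) fell from 13.5 ± 1.04 to 3.14 ± 0.190 CPM, a log2 fold change of -2.09 ± 0.11 (adjusted p = 3.1e-11). Npas2 fell from 5.52 ± 0.902 to 1.30 ± 0.0912 CPM. Several of the 12 encode secreted factors or proteases. The vascular ligand Angpt2 had a log2 fold change of -1.89, the collagenase Mmp13 of -1.59, the Wnt ligand Wnt16 of -1.51, the aggrecanase Adamts4 of -1.41 and the chemokine Ccl9 of -1.28. Ddit4, an inhibitor of mTORC1 signalling (chromosome 10, 59949669 to 59951834), fell from 90.0 ± 2.27 to 36.4 ± 1.74 CPM with an adjusted p of 1.67e-13. The amino acid transporter gene Slc7a8 had a log2 fold change of -1.36 and Bmf, a pro-apoptotic member of the Bcl2 family, of -1.34. Dact1 and Dtx4 both had a log2 fold change of -1.36.

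**Figure D1:**
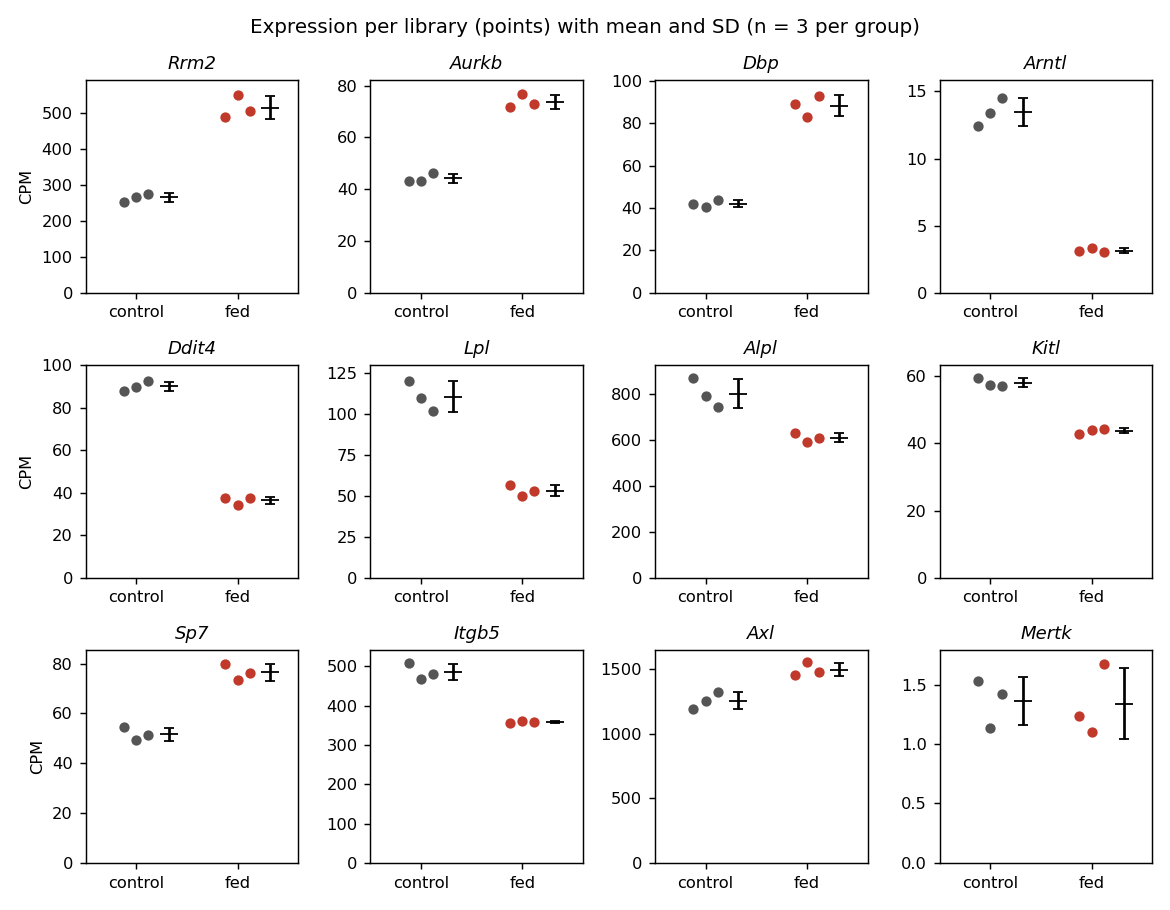
Expression in CPM (vertical axes, from 0) of 12 genes in the 3 control and 3 fed libraries (points), with the mean and SD of each group beside them. Arntl, Ddit4, Lpl, Alpl, Kitl and Itgb5 lay lower in every fed library than in every control library and Rrm2, Aurkb, Dbp, Sp7 and Axl higher, while the groups overlapped for Mertk.

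The lists of DNA replication and mitosis had the smallest camera p of the 38 lists tested. All 30 tested members of the list of S phase and DNA replication rose, with a median log2 fold change of 0.67, and 30 passed when adjusted over the list alone. Camera gave an adjusted p of 1.06e-52 with the preset correlation and adjusted p = 0.265 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, rose from 265 ± 11.8 to 513 ± 31.2 CPM, and Uhrf1, Mcm3 and Pcna had log2 fold changes of 0.77, 0.77 and 0.60. Of 30 mitosis genes, 26 rose and none fell (1 fell without control replicate 1), and 27 were higher when adjusted over the list alone. Their median was 0.51 (camera adjusted p = 8.52e-37, and adjusted p = 0.265 with an estimated correlation). The mitotic kinase Cdk1 rose from 120 ± 4.19 to 194 ± 7.02 CPM, and Aurkb, Ube2c and Prc1 had log2 fold changes of 0.74, 0.69 and 0.59. The genes of cell-cycle arrest and senescence went both ways, with 6 of 17 higher and 6 lower (7 and 6 adjusted over the list alone, camera adjusted p = 0.226). Cdkn2b, Cdkn1a and Cdkn2a, inhibitors of cyclin-dependent kinases, fell by 0.59, 0.22 and 0.25 on the log2 scale, while Ezh2 and Lmnb1 rose by 0.55 and 0.54. The call of Cdkn2a was lost without control replicate 1 (adjusted p = 0.0514) or fed replicate 2 (0.0537). Of 21 p53 targets, 4 rose and 9 fell (6 and 9 adjusted over the list alone, camera adjusted p = 0.465), but 7 rose and 6 fell with library totals only, and 6 and 6 without fed replicate 1.

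Hypoxia and glycolysis genes fell together in fed cells. Of 16 hypoxia response genes, 13 fell and none rose (14 lower adjusted over the list alone), with a median log2 fold change of -0.26. The camera adjusted p was 4.02e-07, and adjusted p = 0.343 with an estimated correlation. Ero1l fell from 118 ± 5.58 to 84.1 ± 1.90 CPM, the collagen prolyl hydroxylases P4ha2 and P4ha1 by 0.38 and 0.32 on the log2 scale, and the oxygen sensor Egln1 by 0.34. Of 21 glycolysis genes, 15 fell and none rose, the same number as adjusted over the list alone (median -0.19, camera adjusted p = 2.56e-05). For these it was adjusted p = 0.343 with an estimated correlation. Pdk1, which restrains pyruvate dehydrogenase, fell from 262 ± 2.81 to 196 ± 6.59 CPM, and Pgk1, Pfkp and Pfkl fell by 0.33, 0.31 and 0.31. The labels give 5% oxygen for the feeding and 2% for the expansion of the cultures and do not give the oxygen of the control wells during the last 24 h.

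None of the 5 mitochondrial lists was called by camera. Of 10 fission genes, 5 rose and none fell, and of 9 fusion and inner membrane genes, 5 rose and none fell, with the same counts adjusted over each list alone. The 5 higher in the fusion and inner membrane list were Chchd3, Oma1, Immt, Afg3l2 and Mfn2, and became 3 without control replicate 2 or by DESeq2. Neither list stood apart from other genes by camera (adjusted p = 0.292 and 0.225). Mtfr2 rose by 0.75, Oma1 by 0.37, Chchd3 by 0.26 and Mtfr1 by 0.19 on the log2 scale. Dnm1l, the dynamin of mitochondrial fission, had a log2 fold change of -0.02 ± 0.041 (adjusted p = 0.692), and Opa1, which fuses the inner membrane, of 0.03 ± 0.048 (0.692). The outer membrane fusion gene Mfn2 rose by 0.12 ± 0.039 (adjusted p = 0.0234), a call lost without control replicate 1 (0.109), control replicate 2 (0.0864) or fed replicate 2 (0.0977) and by DESeq2 (0.0597). Of 75 nuclear-encoded subunits of oxidative phosphorylation, 10 rose, 9 fell and 56 did not pass (9 and 7 adjusted over the list alone, camera adjusted p = 0.911). The balance of these calls was not stable. It was 12 higher and 4 lower with library totals only, 5 and 5 by DESeq2, 4 and 9 without control replicate 1, 8 and 3 without control replicate 2, 13 and 6 without control replicate 3, 12 and 5 without fed replicate 1, 6 and 5 without fed replicate 2, and 5 and 9 without fed replicate 3. Of 13 mitochondrially encoded mRNAs only 7 had enough reads to test. Of these 7, 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.814). The call of the higher, mt-Nd2, was lost without control replicate 2 (0.0941), control replicate 3 (0.0521), fed replicate 1 (0.122) or fed replicate 2 (0.111), and 2 fell without control replicate 2. In the mitophagy list Bnip3, Bnip3l and Pink1 fell by 0.63, 0.52 and 0.33, and Phb2 rose by 0.23. With 3 of 10 members lower and 1 higher, also when adjusted over the list alone, this list had a camera adjusted p of 0.0705 and passed without fed replicate 2 (0.0466) or fed replicate 3 (0.0470).

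**Figure D2:**
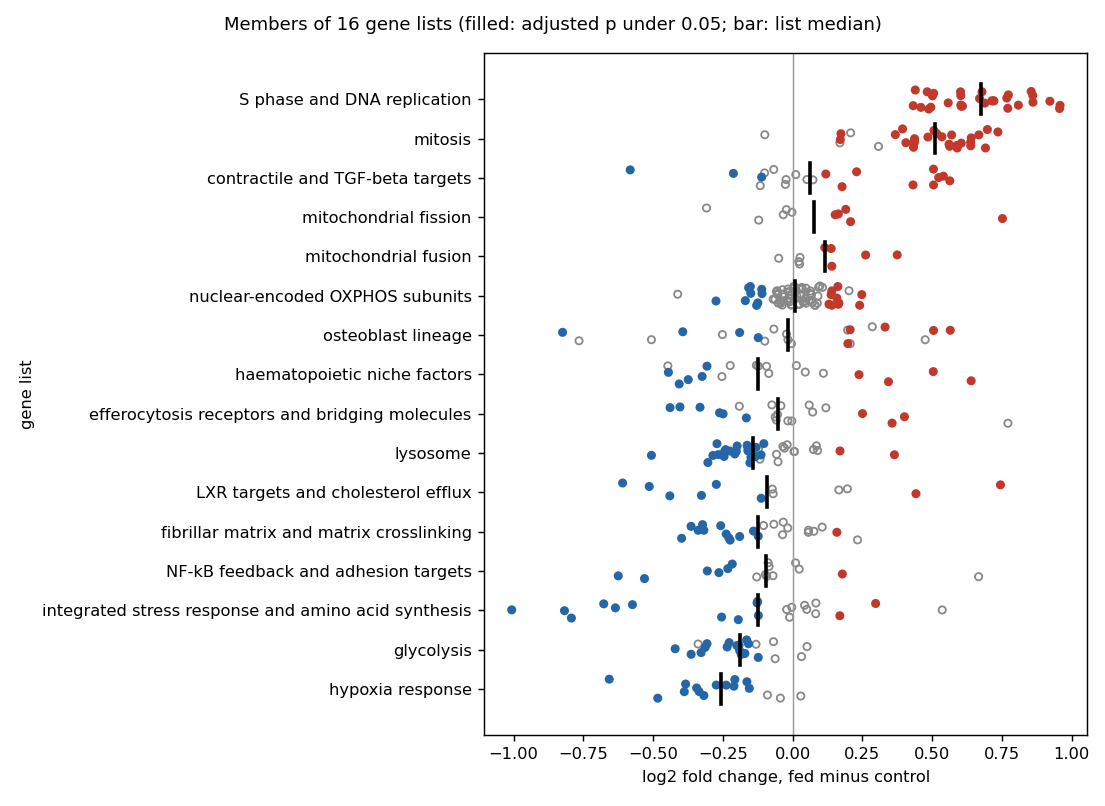
Log2 fold change, fed minus control (horizontal axis), of the tested members of 16 gene lists (rows). Filled points passed an adjusted p of 0.05, red higher and blue lower in fed cells, open points did not, and bars mark list medians, 0.67 for S phase and -0.26 for the hypoxia response.

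Receptors and bridging molecules for apoptotic cells went both ways. Of 21 tested, 3 rose and 6 fell, the same as adjusted over the list alone (camera adjusted p = 0.490). Axl, a receptor for phosphatidylserine bound by Gas6, rose from 1258 ± 66.2 to 1496 ± 50.4 CPM, and Scarb1 and Tyro3 rose by 0.40 and 0.36 on the log2 scale. The integrin gene Itgb5 fell from 486 ± 20.2 to 358 ± 2.83 CPM and the bridging molecule Pros1 by 0.33. Mertk was low in both groups, at 1.36 ± 0.205 and 1.34 ± 0.298 CPM (adjusted p = 0.960).

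Genes of the lysosome fell. Of 36 tested, 22 fell and 2 rose (23 and 3 adjusted over the list alone, 17 and 5 with library totals only, with 0 higher without control replicate 1 and 1 without control replicate 2, fed replicate 1 or fed replicate 3), with a median of -0.14. The camera adjusted p was 0.000482, and adjusted p = 0.343 with an estimated correlation. Pla2g15, a lysosomal phospholipase, fell from 128 ± 2.84 to 90.3 ± 2.58 CPM, and Lamp2, Asah1 and Grn fell by 0.30, 0.29 and 0.24. The other lists of cargo handling were not called by camera. Of 21 autophagy genes, 8 fell and 1 rose, also when adjusted over the list alone (6 and 4 with library totals only, camera adjusted p = 0.0725). The number higher was 0 without control replicate 1 or fed replicate 2, 2 without control replicate 2 or fed replicate 1, and 3 without fed replicate 3, where 6 fell. Among autophagy genes, Calcoco1 fell by 0.44 and Sqstm1 by 0.31. Of 12 LXR targets, 6 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0602, and 0.0490 without control replicate 2, 0.0409 without fed replicate 1 and 0.0470 without fed replicate 3). The cholesterol exporter Abca1 fell from 41.5 ± 3.11 to 30.7 ± 3.54 CPM, Mylip and Scd2 fell by 0.61 and 0.51, and Arl4c rose by 0.74. Of 25 cholesterol synthesis genes, 7 fell and none rose (6 lower adjusted over the list alone, camera adjusted p = 0.0638, under 0.05 without control replicate 2 at 0.0490 or fed replicate 3 at 0.0318), with Hmgcs1 lower by 0.32. Of 24 genes of fatty acid oxidation and PPAR targets, 3 rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.282), with Acadm lower by 0.47.

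Genes of the integrated stress response and amino acid synthesis fell. Of 21, 11 fell and 2 rose, also when adjusted over the list alone (4 higher without control replicate 3, median -0.12, camera adjusted p = 0.000988, and adjusted p = 0.501 with an estimated correlation). The mitochondrial folate enzyme Aldh1l2 fell from 93.9 ± 7.38 to 46.7 ± 1.67 CPM, and Ddit3, Vldlr and Sesn2 fell by 0.79, 0.68 and 0.57. Other stress lists were not called by camera. Of 18 genes of the unfolded protein response, 8 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.577, and 2 lower with library totals only or without control replicate 3, fed replicate 1 or fed replicate 2), with the chaperone Calr higher by 0.24 and Xbp1 lower by 0.34. Of 19 NRF2 targets, 8 rose and 2 fell (8 and 3 adjusted over the list alone, adjusted p = 0.225). The 8 higher became 4 without control replicate 1 and 5 without control replicate 2, fed replicate 1 or fed replicate 2. Among NRF2 targets, Gclc, Txnrd1 and Srxn1 rose by 0.50, 0.44 and 0.38. Of 22 immediate-early and dissociation genes, 5 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.336, and 10 higher by limma-voom and 11 without robust estimation), with Klf4 higher by 0.43 and Socs3 lower by 0.70.

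Osteoblast genes did not move together. Of 21 tested, 5 rose and 4 fell (5 and 5 adjusted over the list alone, and 3 and 3 without control replicate 2), and the median of -0.02 and mean of -0.01 had the opposite sign to the direction of camera (adjusted p = 0.830). Sp7, a transcription factor of osteoblast commitment (chromosome 15, 102356606 to 102367182), rose to 76.5 ± 3.30 CPM in fed cells, a log2 fold change of 0.56 ± 0.048 (SE), and Postn and Ank rose by 0.51 and 0.33. Alpl, the alkaline phosphatase of mineralization, fell from 799 ± 63.5 to 608 ± 19.9 CPM. Runx2 had 55.0 ± 5.26 CPM in control and 54.3 ± 2.41 in fed cells (adjusted p = 0.801). Of 13 adipocyte genes, 3 rose and 6 fell (4 and 6 adjusted over the list alone, 5 and 5 without fed replicate 2, camera adjusted p = 0.292), with the lipase Lpl lower, from 110 ± 9.29 to 53.1 ± 3.26 CPM, and Pparg higher by 0.49. Of 12 chondrocyte genes, 1 rose and 3 fell, also when adjusted over the list alone. It was 2 and 2 without control replicate 1, control replicate 2, fed replicate 2 or fed replicate 3, 3 and 4 by limma-voom, 3 and 3 without robust estimation and 3 and 2 with library totals only. Their median of -0.01 and mean of -0.04 again opposed the direction of camera (adjusted p = 0.931), with Col2a1 higher by 0.39 and Col10a1 lower by 0.72.

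Genes of the fibrillar matrix and its crosslinking fell. Of 23, 12 fell and 1 rose (13 and 2 adjusted over the list alone, 10 and 3 with library totals only, with 2 higher without control replicate 1 or fed replicate 2 and 0 without control replicate 2, control replicate 3 or fed replicate 1), with a median of -0.12 and a camera adjusted p of 0.00677, and adjusted p = 0.501 with an estimated correlation. Plod2, a collagen lysyl hydroxylase, fell from 281 ± 9.98 to 213 ± 4.95 CPM, and Fbn1 and Loxl2 fell by 0.34 and 0.24. P4ha1 and Loxl2, both lower, are also in the hypoxia response list, so the calls of these lists are not fully separate. Of 16 matrix proteases and inhibitors, 9 fell and 3 rose, also when adjusted over the list alone. Their camera adjusted p was 0.0638, and 0.0414 without control replicate 2, 0.0237 without control replicate 3, 0.0468 without fed replicate 1 and 0.0318 without fed replicate 3. Timp3, an inhibitor of matrix proteases, rose to 2703 ± 71.6 CPM in fed cells, a log2 fold change of 0.65 ± 0.038 (SE). Contractile and TGF-beta target genes were called higher, with 9 of 20 higher and 3 lower (9 and 4 adjusted over the list alone, median 0.06, camera adjusted p = 0.0114, and adjusted p = 0.343 with an estimated correlation). Inhba, Ctgf and Tgfb2, which encode secreted proteins, rose by 0.56, 0.52 and 0.43, and the contractile genes Tagln and Myl9 had log2 fold changes of -0.02 and 0.05 that did not pass.

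Factors of the haematopoietic niche also went both ways. Of 19 tested, 4 rose and 5 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.673). Kitl, the stem cell factor, fell from 58.0 ± 1.33 to 43.7 ± 0.790 CPM and Ebf1 by 0.31 on the log2 scale. Csf1, the macrophage growth factor, rose from 1242 ± 40.9 to 1762 ± 47.9 CPM and Nes by 0.64. Cxcl12 had 1937 ± 222 CPM in control and 1421 ± 170 in fed cells, an adjusted p of 0.0538 that missed the threshold. It was 0.0136 without fed replicate 2, 0.00568 by DESeq2 and 0.000379 by limma-voom. Of 17 cytokines and chemokines, 7 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.884), and 6 and 4 without control replicate 3. Ccl9 fell from 158 ± 17.7 to 65.0 ± 4.94 CPM and Cxcl5 by 0.44, Ccl2 rose by 0.33, and Il6 had a log2 fold change of 0.10 ± 0.13 (adjusted p = 0.571). NF-kB feedback and adhesion genes fell, 6 of 16 against 1 higher, also when adjusted over the list alone (camera adjusted p = 0.0228, and adjusted p = 0.501 with an estimated correlation). Without control replicate 1 their camera adjusted p was 0.0519, and none was higher without control replicate 2 or fed replicate 2. Bcl3 and Tnfaip2 fell by 0.63 and 0.53.

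Interferon-stimulated genes were set apart by a single control library. Their median in control replicate 3 lay 1.42 (log2) above the mean of the other 2 control libraries, while every other library lay between -0.37 and 0.20. Of 24 tested, 5 were called lower and 1 higher (1 and 1 adjusted over the list alone), with a median of -0.76 and a camera adjusted p of 0.0859. The number lower rested on the fit and on single libraries. It was 16 without robust estimation and 3 with library totals only, 2 without control replicate 1, 7 without control replicate 2, 1 without fed replicate 1 or fed replicate 2, and 2 without fed replicate 3. Without control replicate 3 the median was -0.28, with 7 lower and 3 higher, and none was higher without control replicate 1, control replicate 2 or fed replicate 2. Without control replicate 2 the list passed (camera adjusted p = 4.98e-05). The guanylate-binding protein gene Gbp2 fell from 36.8 ± 5.99 to 24.3 ± 1.09 CPM. Of 15 antigen presentation genes, 5 fell and none rose (3 lower adjusted over the list alone, adjusted p = 0.101, passing without control replicate 2 at 0.0153 with 8 lower, against 2 lower with library totals only, 3 without fed replicate 2 or fed replicate 3, and 3 lower and 1 higher without control replicate 3), with H2-Ab1 and Tap2 lower by 0.32 and 0.27.

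**Figure D3:**
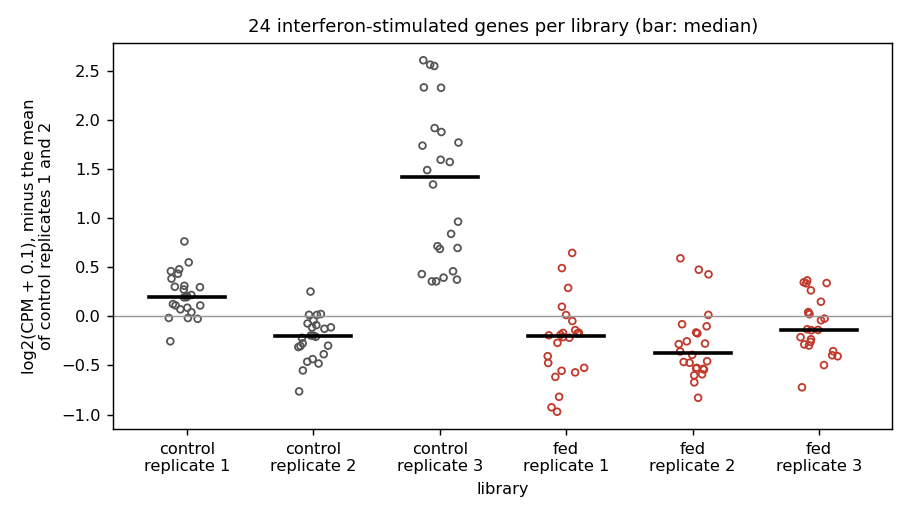
Log2 of CPM plus 0.1 for 24 interferon-stimulated genes (open points) in each of the 6 libraries, relative to the mean of control replicates 1 and 2, with bars at the medians. Control replicate 3 has a median of 1.42, and the other libraries lie between -0.37 and 0.20.

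Markers of thymocytes and macrophages were low in all libraries. The thymocyte list summed to 16.0 ± 0.403 CPM in control and 15.2 ± 1.15 in fed cells, most of it from 3 tested genes, of which Trac, a T-cell receptor constant region, fell by 0.30, also when adjusted over the list alone (camera adjusted p = 0.621). The macrophage list summed to 15.2 ± 0.763 CPM in control and 22.8 ± 1.02 in fed cells. Of its 5 tested members 3 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.225). These were Lyz2, Cd14 and Mpeg1, and Lyz2 rose from 3.32 ± 0.659 to 7.47 ± 0.866 CPM. The adjusted p of Cd14 was 0.0490 and lay above 0.05 in all 6 fits without 1 library, from 0.0502 without fed replicate 2 to 0.223 without fed replicate 1. The Cd14 call was also lost by DESeq2 (0.166), by limma-voom (0.0592), with upper-quartile normalization (0.0579), without robust estimation (0.0558) and with either other filter (0.0683 and 0.0510). That of Mpeg1 was 0.0280, and 0.122 without control replicate 1 or control replicate 2, 0.0595 without fed replicate 2, 0.0987 without fed replicate 3 and 0.113 by DESeq2. Of 3 neutrophil genes, S100a8 rose and Prtn3 fell, also when adjusted over the list alone (camera adjusted p = 0.909), and Prtn3 was lost without control replicate 2 (0.0848) or fed replicate 2 (0.0615, at a log2 fold change of -0.65 against -1.02). S100a8 went from 0.176 ± 0.0659 to 0.777 ± 0.266 CPM. Of 5 endothelial genes Vwf fell, at 2.79 ± 0.377 and 1.70 ± 0.461 CPM, and of 4 osteoclast genes Ctsk fell by 0.17, also when adjusted over each list alone (camera adjusted p = 0.932 and 0.910). The median of the osteoclast list, 0.04, had the opposite sign to the direction of camera. The lists of B cells and erythroid cells had 1 tested member each, Ebf1 and Epor, which both fell, and were not tested as lists. They summed to 177 ± 7.25 and 1.06 ± 0.112 CPM in control and 143 ± 5.53 and 0.468 ± 0.110 in fed cells. Nearly all of the B cell sum was Ebf1, also listed among the niche factors, and its other 10 members held 22 reads in control and 22 in fed libraries. Of 18 mesenchymal stromal markers, 6 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.947), with Cd44 and Cspg4 higher by 0.58 and 0.75 and Thy1 lower by 0.38. The median of -0.09 and mean of 0.04 of this list differed in sign.

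Over all 38 lists tested, 9 were called by camera, 3 higher and 6 lower. With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.265, and fry called 22.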

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

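The second marker lists used below were chosen after the reads of the first lists had been seen, and before their own reads were counted. Members of the thymocyte list too low for the test held 148 reads over the fed libraries (49, 49 and 50) and 48 over the control libraries (14 to 19 each). Members of the macrophage list too low for the test held 174 reads in fed (48 to 67 each) and 27 in control (7 to 11 each). For both lists every fed library lay above every control library in CPM. Such members of the neutrophil list did so too, with 9 reads in fed (2 to 4 each) against 2 in control (0 to 2 each). Among thymocyte genes Rag1, part of the antigen receptor recombinase, had 25 reads in fed and 3 in control, Dntt 9 and 0, and Cd8b1 7 and 0. Among macrophage genes C1qc had 25 and 0, Msr1 22 and 0, and C1qa 18 and 0. Over group totals of 63964771 counts in fed and 62485146 in control, these are traces, at 2.30 ± 0.119 CPM for the thymocyte and 2.71 ± 0.565 CPM for the macrophage members in fed libraries (SD, n = 3). Groups of 3 libraries were not tested for outlying samples.

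Macrophage RNA that came along with the thymocytes is a candidate explanation for the macrophage reads. In the second macrophage list, 17 of 18 members with reads but too low for the test were higher in fed libraries, a share of 0.944, with 138 reads against 36. Blood cells were removed before culture and, per the labels, flow cytometry found no macrophages in the cultures, but the final sort took label-positive cells and the labels name no macrophage gate there. For RNA of the fed thymocytes the second list left the matter open, with 10 of 16 members higher, a share of 0.625, and 80 reads against 57, so this source and low expression in the stromal cells cannot be told apart for that list. Of the first list, 5 of 19 members were high enough to test in these cells, and of those above 1 CPM Lyz2 rose from 3.32 to 7.47 CPM and Cd14 from 4.28 to 5.36 CPM (adjusted p = 0.0490, above 0.05 without any 1 library and by DESeq2 or limma-voom) while Csf1r and Cd68, at log2 fold changes of -0.09 and 0.18, did not pass, and expression of such genes by stromal cells after uptake was not tested and stays open.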

How the results depend on the processing

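The tests of glucocorticoid targets and of the second macrophage list were chosen after the data were seen. The count of 5175 changed genes was 5848 with the replicate number as a replicate block, 3963 by DESeq2, 3615 at an adjusted p under 0.01, and 4145 to 5088 without 1 library. Other normalizations, filters and tests gave 5119 to 5212. Of the genes called, 3922 were shared with DESeq2 and 4710 with library totals only, where 61.1% of calls were higher against 51.8%. No shared gene changed direction. Tested against a 1.5-fold change, 88 genes passed, 48 higher and 40 lower, since that test asks for a larger effect. The correlations of deviations between libraries of the same number were 0.10, 0.02 and 0.13. Control replicate 2 was slightly closer to fed replicate 1 (0.027) than to fed replicate 2 (0.022), while every other library matched its own number best. The second principal component also ran in the order of the numbers in both groups. These values and the labels do not settle a pairing, so the block stayed an alternative. It raised the lists called from 9 to 13 and ended no list call, and gave 14 immediate-early genes higher against 5, and 8 interferon-stimulated, 8 antigen presentation and 8 niche genes lower against 5 of each, and 4 chondrocyte genes higher and 4 lower against 1 and 3. With it mt-Nd2 lost its call (0.214), and the genes higher were 3 against 1 for autophagy and for the fibrillar matrix. Camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, 22. Without 1 library 8 to 14 lists were called, the 14 without control replicate 2. The cause was not tested for these. Of 161 named genes called, 146 kept their call and direction in every alternative but the 1.5-fold test, and 26 in that test too. Changes of sign were seen for 13 results, none past the threshold. With library totals only the log2 fold change was 0.015 for Mertk, 0.0089 for Dnm1l and 0.010 for Runx2. Without 1 library it ran from -0.22 to 0.11 for Mertk, -0.051 to 0.0068 for Dnm1l, -0.083 to 0.052 for Runx2, -0.012 to 0.073 for Opa1 and -0.0021 to 0.24 for Il6. The direction of camera turned, with adjusted p between these values without 1 library, for mesenchymal stromal (0.830 to 0.981, and 0.935 by fry and 0.937 with library totals only), nuclear-encoded OXPHOS subunits (0.481 to 0.939), cytokines and chemokines (0.307 to 0.985), chondrocyte lineage (0.716 to 0.935), endothelial (0.816 to 0.981), mitochondrially encoded mRNAs (0.365 to 0.981) and glucocorticoid targets (0.710 to 0.985). That of the second macrophage list turned with at least 1 CPM in at least 3 libraries (0.476). The cause was not tested for these. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes. The highest other split gave 0 with edgeR (604 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Every other split put fed and control libraries in both of its groups. The difference between fed and control then widened the spread, so low counts there do not measure chance. At this depth 14 of 19 macrophage and 25 of 28 thymocyte markers were too low to test. Of simulated changes of 0.25 (log2) the test recovered 44.0%, which may be too low, as far fewer genes were changed there than called here.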

Other observations

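The gene lists and the tests of clock genes in this part, and the bound used for thymocyte RNA, were chosen after the data were seen, while the tests of GC content and of single libraries were fixed before their results. These lists were adjusted over 9 lists only, so their adjusted p cannot be set beside those over the 38 fixed lists. Feedback targets of the ERK pathway rose in fed cells, 12 of 16 against 1 lower (median log2 fold change 0.57, camera adjusted p = 3.56e-07, and adjusted p = 0.0204 with an estimated correlation). The phosphatase gene Dusp6 had a log2 fold change of 0.78 ± 0.11 (SE), Etv5 of 0.55 ± 0.057 and Ccnd1, cyclin D1, of 0.71 ± 0.041. The EGF family ligands Ereg and Hbegf rose from 8.23 ± 0.977 to 16.0 ± 1.08 CPM and from 18.6 ± 0.801 to 33.7 ± 3.76 CPM (SD, n = 3), and as 2 of 4 members they gave a camera adjusted p of 0.00709, and adjusted p = 0.0918 with an estimated correlation. BMP target genes rose, 8 of 12 with none lower (median 0.51, camera adjusted p = 2.7e-10, and adjusted p = 0.0271 with an estimated correlation). Id4, Atoh8 and Smad6 had log2 fold changes of 0.63, 0.59 and 0.54.

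Genes induced by FOXO factors or starvation fell, 14 of 18 against 1 higher (median -0.35, camera adjusted p = 8.66e-12, and adjusted p = 0.0204 with an estimated correlation). Fbxo32, a ubiquitin ligase of muscle atrophy, fell from 83.2 ± 5.99 to 42.3 ± 0.687 CPM, and Arrdc4, Ccng2 and Foxo3 fell by 0.65, 0.49 and 0.32, while Foxo1 rose by 0.24. As these lists were written from the same libraries, their p-values describe them and are not independent evidence.

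Genes of S phase and mitosis were higher in fed cells, which could come from a technical source. RNA of the fed thymocytes, which include dividing cells, would bring thymocyte genes along. The summed CPM of the S phase and mitosis lists went from 5103 ± 123 to 7401 ± 217 and that of the thymocyte list from 16.0 ± 0.403 to 15.2 ± 1.15 (SD, n = 3), and the largest ratio of the rises in any fed library was 0.000228. Most of the thymocyte sum was Trac, which control cells already held and which fell from 12.2 to 9.91 CPM, so this ratio can miss thymocyte RNA. The thymocyte members too low for the test rose from 0.786 ± 0.187 to 2.30 ± 0.119 CPM, far less than the S phase and mitosis lists. After a smooth trend on GC content and transcript length was removed, the median of the 60 genes was 0.56 (0.59 before), and every fit without 1 library called at least 56 of them, so a trend of this kind and a single deviating library are argued against. Thymocyte RNA is argued against only by the sizes of the rises, since its bound was set after the data were seen. Whether uptake changed the cells or label-positive cells differed beforehand was not tested and stays open, as does the medium weighed for the clock genes next.

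Clock genes moved in opposite directions. Of 5 genes with ROR elements, Arntl, Npas2, Nfil3 and Clock fell (median -1.16), and of 11 genes with E- or D-boxes 6 rose, among them Dbp (log2 fold change 1.07 ± 0.049, SE), Nr1d1 and Per2, and Bhlhe40 fell (median 0.33). A shift in the phase of the clock between the groups at harvest may give such values, a hypothesis that they cannot test, since the lists were written after members such as Arntl and Npas2 had been seen to move and each group was sampled at a single time. Glucocorticoid exposure, which can set the clock, was left open, with the median of its targets at percentile 71.3 and members going both ways (2 of 9 higher, 3 lower, camera adjusted p = 0.862). Medium given together with the thymocytes may also shift the clock, but the medians of the FOXO and starvation genes (-0.35) and the ERK feedback genes (0.57) decide nothing, as these lists too were written after members had been seen to move, and as the labels do not say whether control wells received new medium it cannot be told apart from the thymocytes themselves.

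The second marker lists, over the members that could be tested, were not called by camera. The second macrophage list had 1 of 8 higher and 1 lower (camera adjusted p = 0.820) and the second thymocyte list 1 of 9 higher and 4 lower (0.562). By fry the adjusted p was 0.224 for the second macrophage list and 0.0258, under the threshold, for the second thymocyte list. The tested members of the second thymocyte list had a median log2 fold change of -0.17, and camera gave its direction as lower in fed cells. In the second macrophage list the actin-bundling gene Lcp1, typical of leukocytes, rose from 0.0821 ± 0.0314 to 0.797 ± 0.212 CPM (SD, n = 3, edgeR adjusted p = 4.22e-05). The member called lower, Cd53, was more expressed and fell from 4.58 ± 0.238 to 2.93 ± 0.135 CPM (edgeR adjusted p = 0.000822).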
